A study of Homo sapiens with 2 samples.

How the data were processed

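Gene expression was measured in 2 RNA samples of MDA-MB-231, a human breast cancer cell line of triple-negative, mesenchymal-like type. One sample came from clone 9, a clone that stably overexpresses human SUV420H2 after transfection. The other came from the untransfected parental line. SUV420H2, now named KMT5C, is the methyltransferase that trimethylates histone H4 on a lysine residue typical of constitutive heterochromatin. Per the labels' protocols, both cultures were kept in medium with 10% serum, and column-purified total RNA was amplified to aminoallyl RNA, coupled to Cy5 and hybridised alone. Each group therefore held 1 array of 1 colour. The labels list no second culture, second clone or vector-transfected control.

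Per the file headers, the arrays were of a Toray human 25k design, version 2.1, scanned at 635 nm, and the header fields for normalization and background subtraction were empty. The deposited scanner files give the median pixel intensity of each spot and of its surroundings on a linear scale, neither corrected nor normalized. The software version used to extract them was not given in the sources used here. The authors also deposited a table of processed intensity values, whose calculation was not given in the sources used here. Set against the scanner values, each of its columns followed the spot intensity on a straight line (Pearson r = 0.999993 across probes for the clone and 0.999991 for the parental line). The lines crossed 0 at a spot intensity of 26.3 and 27.3, close to the blank spots. Both columns had a median of 25 over the listed probes, and 2837 and 2422 probes had no value. These values are thus linear intensities with a common median, with 1 column per sample and no ratio whose direction could be in doubt. No column belonged to a sample outside the series.

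Each array carried 27456 spots, of which 24460 were gene probes, each spotted once, and 2996 were control spots. The scanner had marked 1 gene spot as bad on the clone's array and 2 on the parental array. These 3 probes were left out, which left 24457. Background was corrected with normexp (limma 3.58.1 in R 4.3.3) with an offset of 50, fitted to all spots of an array. Control spots were then removed, and the log2 values were quantile-normalized between the arrays. The local background column was not subtracted, a choice made after the files were seen. Across probes its log2 value followed that of the spot itself (Pearson r = 0.917 on the clone's array and 0.982 on the parental array), so it held spot signal. A probe counted as above background when its intensity exceeded the mean of the 2680 blank spots by 2 SD, which came to 30.9 on the clone's array and 32.2 on the parental array. Differences are log2 clone minus log2 parental. Because 50 is added to every intensity, they understate the change of dim probes.

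With 1 array per group there is no residual spread, so no test was made and no p-value is given. Probes are described by size of difference, at a threshold of 2-fold. The robust SD (scaled median absolute deviation) of the log2 differences within 20 equal brightness bins stands beside single probes. It is a spread across probes, not across replicates. Repeated control spots gave the spot-to-spot error within an array. The number of arrays limits the precision of every value.

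The files used here name gene probes by the manufacturer's identifiers, and the platform's gene annotation was not used here. A gene name could be given only to 1 probe whose identifier holds a RefSeq transcript accession, which a RefSeq gene table of GRCh38.p14, used for the name only, gave as KRT8. The table of gene names used here matched no other probe. The plan fixed before the data were examined named SUV420H2, its relatives SUV420H1 and SETD8, tensin-3 (TNS3), the 15 genes with the largest difference each way and genes above background on 1 array only, together with 37 gene lists holding 1156 genes. A list needed 5 named members to be described. KRT8 belonged to 2 of the lists, and no list had more than 1 named member, so the lists and the other planned genes are not analysed here. From the rule on largest differences, 2 probes each way are given by identifier. These were the largest differences among probes above background on both arrays and at or above the median level of such probes. The remainder of that rule is given as counts and ranges.

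The steps were tested on simulated data for this comparison. The parental array was given the spot-to-spot noise of the positive controls (log2 SD 0.100), and 200 of the 24457 probes were changed by a known factor. At a simulated change of 4-fold, 88% of the changed probes were called at 2-fold, and at 2.5-fold 59% were. The median fitted change was 3.20-fold and 2.09-fold. No unchanged probe was called and no direction was wrong. The simulated noise was that of repeated bright control spots within an array. It left out culture, labelling, hybridisation and any added noise of dim spots. Noise of that size lies far below the 2-fold threshold, so false calls and wrong directions were hardly possible in this setting. Their absence gives no error rate for the comparison of the clone with the parental line.

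Alternatives planned before the data were examined were median scaling, cyclic loess or no normalization between arrays, no background correction, an offset of 16, plain subtraction of the blank level with a floor at 2 blank SD, the authors' processed values, other filters on dim probes, and thresholds of 1.5-fold and 3-fold. Subtraction of the local background before normexp, normexp fitted to the blank and negative control spots, removal of the median of each print block and retention of the spots marked bad were added after seeing the data.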

Results

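The data comprised 2 Cy5 arrays, 1 from an MDA-MB-231 clone that stably overexpresses SUV420H2 and 1 from the parental line. They compare gene expression between this clone and its parental line. They cannot separate raised levels of this heterochromatin methyltransferase from the choice of clone, transfection or culture. Each array held 24457 usable gene probes. In the clone, 20200 probes (82.6%) were above background, with a median raw intensity of 58 and a 99th percentile of 7200. In the parental line, 19345 probes (79.1%) were above background, with a median of 60 and a 99th percentile of 7065. No gene probe reached the scanner's maximum. Blank spots read 26.7 ± 2.13 (SD over 2680 spots) on the clone's array and 27.7 ± 2.26 on the parental array. There were no replicate cultures or arrays, and none of the differences below has a replicate check.

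The transfected gene could not be used to check the labels, because the files used here name no probe for SUV420H2 and the platform's gene annotation was not used here, so its level is not analysed here. The same holds for tensin-3 (TNS3), a focal adhesion protein that later work on this line addressed.

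Most probes read alike in the clone and the parental line. Of the 20646 probes above background on at least 1 array, 99.5% differed by less than 2-fold. The central 95% of log2 differences lay between -0.42 and 0.47, that is, between 1.34-fold lower and 1.39-fold higher in the clone. The levels correlated across probes with Pearson r = 0.991 and Spearman rho = 0.983; this is across probes, which are not independent replicates. At 2-fold or more, 61 probes (0.295%) were higher and 38 (0.184%) were lower in the clone. In the authors' processed values, where no offset holds dim probes together, 335 probes were 2-fold higher and 264 lower among 21201 probes listed on both arrays. These included 60 of the 61 higher and 36 of the 38 lower probes, an overlap between 2 treatments of the same spot intensities. The 2 arrays cannot show how many of the differences would recur in a second culture.

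Among the larger differences more probes were higher than lower in the clone, by a margin that depended on the processing. In the normexp values, at 3-fold, 19 probes were higher and 3 lower. At 4-fold, 12 were higher and 0 lower, and 4 probes were over 8-fold higher. The authors' processed values had a median log2 difference of -0.08, against 0 in the normexp values. The authors' values were more even, with 92 higher and 70 lower at 3-fold, 48 and 26 at 4-fold, and 11 and 7 at 8-fold. Among the 6378 probes with a raw intensity of at least 200 on either array, those values gave 18 higher and 2 lower at 4-fold, against 12 and 0 in the normexp values. Among the 9454 probes that were above background on both arrays and at or above their median level, the 15 largest increases ran from 3.27-fold to 10.2-fold (median 6.01-fold). The 15 largest decreases ran from 2.34-fold to 3.64-fold (median 2.88-fold). All 30 had the same direction in the authors' values. Those follow the same spot intensities on a straight line, so this is no separate check.

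**Figure D1:**
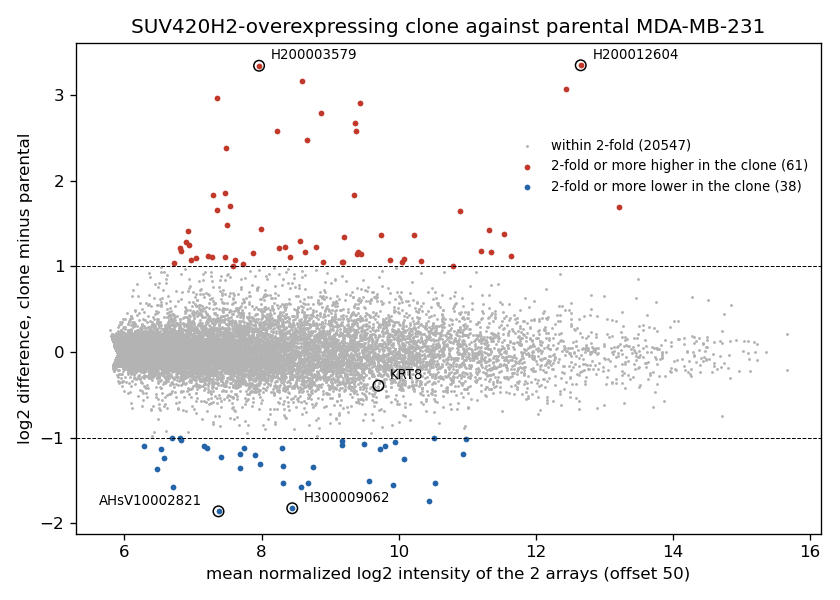
Log2 difference (clone minus parental) against mean normalized log2 intensity for the 20646 probes above background on at least 1 array, each point 1 probe; dashed lines mark 2-fold, and circles mark the probes named in the text. The 61 higher probes reach 3.35 on the log2 scale, whereas the 38 lower ones end at -1.86.

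Of the probes named by the rule on largest differences, H200012604 was the brightest. It read 20886 raw units in the clone and 1962 in the parental line, a log2 difference of 3.35 (10.2-fold higher), and 10.4-fold in the authors' values. The robust SD of log2 differences at its brightness was 0.247. The probe H200003579 read 775 in the clone and 51 in the parental line, a log2 difference of 3.34. Its fold was 10.2 with the offset and 28.5 in the authors' values; its parental signal lay not far above the background threshold of 32.2. On the lower side, AHsV10002821 read 58 in the clone and 286 in the parental line, a log2 difference of -1.86 (3.64-fold lower; 8.66-fold in the authors' values). For H300009062 the readings were 157 and 624, a log2 difference of -1.83 (3.55-fold lower; 4.59-fold in the authors' values). The genes of these 4 probes were not looked up here.

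KRT8, which encodes keratin 8, the type II intermediate filament protein of simple epithelia, was the only gene named from the files used here. Its probe was well above background on both arrays, at 699 raw units in the clone and 917 in the parental line. The log2 difference was -0.39 (1.31-fold lower in the clone), and -0.46 in the authors' values. The robust SD among the 1032 probes of like brightness was 0.273, and 82.5% of them had a smaller difference, so KRT8 lay inside the spread of probes at its level. It did not reach 2-fold. KRT8 has many processed pseudogenes, and whether this probe also binds their transcripts was not examined. With the local background subtracted, the sign turned to a log2 difference of 1.37, because that column read 215 beside the clone's spot and 875 beside the parental one.

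In the normexp values, few probes were present in 1 of the lines alone by a wide margin. Both arrays detected 18899 probes, and neither detected 3811. A further 1301 probes were above background in the clone alone and 446 in the parental line alone. Their bounds were the bright array's normalized level over the higher of the dim probe's own level and the lowest level above background on that array. Only 1 of the 1301 was at least 2-fold higher in the clone by this bound, at least 7.54-fold. Only 1 of the 446 was at least 2-fold higher in the parental line, at least 2.41-fold. In the authors' table the balance was the other way, with 419 probes listed for the clone alone and 834 for the parental line alone.

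Repeated control spots gave the spot-to-spot error within an array. Positive control 1 read 46411 ± 2185 (SD over 24 spots) on the clone's array and 46618 ± 2304 on the parental array. Positive control 2 read 9807 ± 928 and 11686 ± 954. It was lower on the clone's array at 24 of 24 positions, by a mean log2 difference of -0.25 ± 0.110 (SD over positions), whereas control 1 differed by -0.01 ± 0.0743. These are spots on a single pair of arrays, and their SD leaves out culture, labelling and hybridisation. The spread between the arrays depended on brightness and on the processing. In the normexp values the robust SD of log2 differences grew from 0.0725 in the dimmest 20% of probes to 0.263 in the brightest 20%. In the authors' values, binned over the probes listed there on both arrays, it was 0.443 in their dimmest 20% and 0.284 in their brightest.

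**Figure D2:**
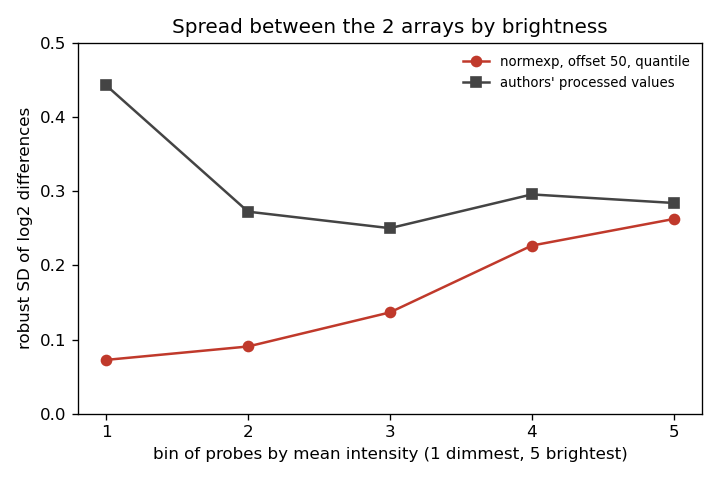
Robust SD of the log2 differences between the 2 arrays in 5 equal bins of the probes by mean intensity, for the normexp values (circles) and the authors' processed values (squares), each point 1 bin. The bins of the 2 treatments do not hold the same probes. Those of the normexp values split the 20646 probes above background on at least 1 array, and those of the authors' values the 21201 probes listed on both arrays. The 2 treatments lie close together in the brightest bin (0.263 and 0.284) and far apart in the dimmest (0.0725 and 0.443).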

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

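The tests in this part were set down before their values were computed, but after the counts of 2-fold probes and the signal of the spot below had been seen. One result stood out in data that the comparison leaves out. A gene spot that the scanner had marked as bad read 47145 raw units on the clone's array and 54 on the parental array, where it was marked good. Only 2 gene probes on the clone's array were as bright or brighter, it has no value for the clone in the authors' table, and with the 3 marked spots kept the 2-fold count became 62 higher and 38 lower. Spill from its neighbours is argued against, since the brightest of the 8 adjoining spots had 5.99% of its signal. The spread of its pixels over their mean was 0.535, against a median of 0.147 and a 95th percentile of 0.237 among the 179 gene spots brighter than 10000 on that array; this is the 100th percentile, which is consistent with a speck or smear on the spot. The local background beside the spot was 7657 on the clone's array and 37 on the parental array. An uneven spot can also hold true signal, so the pixel spread alone does not decide the matter. A transcript present in the clone alone stays open, since the number of further spots of this probe was 0.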

How the results depend on the processing

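No paired analysis was possible because each group has 1 array; leaving out a replicate was likewise not run, nor were those for gene lists, for the probe chosen per gene, for SUV420H2 and for TNS3. The counts at 2-fold, 61 higher and 38 lower in the clone, stayed within 1.5 times under median scaling, cyclic loess, no normalization between arrays, both filters on dim probes and, among alternatives added after seeing the data, normexp fitted to blank and negative spots, removal of print block medians and retention of marked spots. Dropping the filter on dim probes could not move them, since the offset keeps probes below background on both arrays from reaching 2-fold. The normalizations moved the median of all probes by only 0.0178, so they were a weak check. The counts moved with the background treatment. With no background correction 104 were higher. An offset of 16 gave 118 higher and 63 lower, and plain subtraction 372 and 264. The authors' values, which also differ in scaling and in the probes counted, gave 335 and 264. A smaller offset shrinks dim differences less, by its construction. With the local background subtracted there were 915 higher and 412 lower, of which 22 and 14 were among the 61 and 38. The local background differed between the arrays, with a median of 33 on the clone's array and 45 on the parental array. It was at or above the spot for 2.70% of gene probes on the clone's array and 9.40% on the parental array. The cause of the changed counts was not tested. At 1.5-fold there were 302 higher and 192 lower, and at 3-fold 19 and 3. More probes were higher than lower under every alternative run, from 55.9% of those at 2-fold in the authors' values to 69.0% with local subtraction (86.4% at the 3-fold threshold). KRT8 kept its direction except with local subtraction (1.37). The 4 other probes kept theirs throughout: H200012604 ranged from 3.34 to 3.45 on the log2 scale, H200003579 from 2.41 to 4.99, AHsV10002821 from -3.11 to -0.49 and H300009062 from -2.21 to -1.45. Signal over background limits the dim probes, where the treatment of background sets the size of a difference.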

Other observations

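The 2-fold probes were spread unevenly over the array's probe series, which the manufacturer's identifiers distinguish by their opening letters. Of the probes whose identifiers open with H, 11612 were above background and 38 were 2-fold higher and 23 lower (0.525%). In the AHsV series, 9 of 2401 were higher and 9 lower (0.75%), and in the opHsV series 8 of 2725 were higher and 4 lower (0.44%). The CHsGV series had 5 higher and 2 lower of 1786. The DHsGV series had 1 higher and 0 lower of 2045 (0.0489%), with a median raw intensity over its probes of 39, against 82.5 in the H series. The AHsV series, with the largest share, had a median of 44. These medians are over all probes of a series, whereas the shares are over those above background (71.6% of AHsV and 80.5% of DHsGV probes). Whether brightness orders the shares was not tested. What the letters stand for is not given in the sources used here.

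The raw intensities are whole numbers, so that the lowest intensity counted as above background was 31 on the clone's array and 33 on the parental array. The excess of probes above background in the clone alone (1301 against 446) was not seen in the authors' list (419 against 834). The rule by which that list holds a probe was not given in the sources used here.

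The tests in this and the next paragraph were set down before their values were computed, except the count per print block, the count of bright probes and the medians by brightness, which were chosen after the result was seen. For the 99 probes at least 2-fold apart, the tables argue against gathering in some print blocks, since each of the 24 blocks held 2 to 7 of them. The variance per block was 0.407 times the mean, below the central 95% of 10000 random placements (0.513 to 1.65). They were thus spread more evenly than in most random placements, and the reason was not examined. The tables also argue against spill from adjoining spots, since the median log2 difference of 164 side neighbours, signed along the probe, was -0.0202. Scaling as the cause of the differences is argued against, since without normalization no median of the 20 brightness bins lay further than 0.0583 from 0. Of the 99 probes, 46 lay in the brightest 20% by the authors' offset-free values, were 2-fold apart in them and had a dimmer raw intensity of at least 144. These 46 were not dim on either array, so noise of dim probes does not apply to them. They were picked for brightness, so the count does not weigh that noise for the 99 as a set. The remaining values decided nothing: the 96.0% that stayed past 2-fold with block medians removed, as these spanned only -0.03 to 0.02; the 4.71 percentage points by which the share of higher probes moved over 4 normalizations, as these moved the median of all probes by only 0.0178; and the 87.9% at or above the median level, as the offset of 50 itself keeps dim probes from reaching 2-fold. Position on a finer scale, noise of dim probes for the other 53 and scaling for the lean towards higher probes stay open. Whether SUV420H2 overexpression, the choice of a single clone, transfection or culture could account for the differences also stays open. The number of further clones or vector controls among the arrays is 0.

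Plain subtraction of the blank level brought a further 537 probes past 2-fold, with a median raw intensity of 41, and 83.4% of them lay under the median level of probes above background on both arrays. Noise of dim probes may account for many of these: 71.3% fell under 2-fold once both intensities were moved against the difference by 2 SD of the blank spots. That is short of the 75% set beforehand for calling noise the cause and above the 25% that would have excluded it, so it stays open.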
